A study of Mus musculus with 18 samples.

How the data were processed

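The series holds RNA sequencing of MC3T3-E1 cells, an established mouse pre-osteoblast line, on 3 membranes without and with daily ultrasound, with 3 libraries in each of 6 groups. Polyadenylated RNA was sequenced by standard Illumina protocols, per the labels. Reads were trimmed with cutadapt 1.9 and inspected with FastQC, and the genome build was GRCm38, per the submitters' processing notes. The aligner, the counter and its treatment of strand and of reads shared between genes are not given in the sources used here. The authors deposited 1 table with whole-number counts per gene and library, not normalized, and FPKM values (fragments scaled to transcript length and library size), both named per the file headers. The ratio of a gene's count to its FPKM and the library total had a median coefficient of variation of 1.43% over libraries. Gene coordinates are those of the table, on GRCm38. Each library was placed in its group by its title or treatment label.

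The table held 30452 genes, of which 11936 reached an FPKM of 1 in at least 3 libraries and were tested. Counts were normalized by TMM, with all 18 libraries in 1 fit with a mean per group and 12 residual degrees of freedom, and tested by edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3). Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each contrast, with no fold threshold. The design fixed before the data were examined had named limma (version 3.58.1) with an intensity trend on log2(FPKM + 1), because the table was announced as FPKM. The table also held counts, so edgeR became the main test and that limma fit an alternative. The common biological coefficient of variation was 0.28. Depth was 48307580 to 78039543 counts per library, so the spread between libraries and not counting error limited precision for the named genes. The contrasts were ultrasound on each membrane, zinc oxide (PLLA/ZnO against PLLA) and collagen (PLLA/ZnO@Col against PLLA/ZnO) without and with ultrasound, the average of the ultrasound contrasts and their differences between membranes.

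Of 30 gene lists fixed before the data were examined, 26 had at least 5 tested genes and were tested by limma's camera with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. An estimated correlation and fry were alternatives. For ultrasound on PLLA the estimates were 0.751 for ribosomal proteins, 0.74 for mitochondrial transcripts, 0.547 for nuclear oxidative phosphorylation and 0.266 for immediate early genes. They lay near or below the preset only for the osteoblast (-0.0199), osteocyte (-0.0437) and zinc (0.011) lists. Where the estimate is higher, the preset makes p-values too small, and a call at the preset alone is weak. The lists covered osteoblast differentiation, matrix, collagen processing, matrix proteases, integrins, YAP and TAZ targets, contractile actin, mechanosensitive and calcium signalling, immediate early genes, zinc and metallothionein, antioxidant genes, ER stress, heat shock, cell cycle, BMP and TGF-beta, Wnt, inflammatory cytokines, interferon response, glycolysis and hypoxia, nuclear oxidative phosphorylation, cholesterol synthesis, mitochondrially encoded transcripts, ribosomal proteins, and markers of osteocytes, adipocytes, chondrocytes, fibroblasts, macrophages, endothelium and epithelium.

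The rule for named genes took, per contrast, the 5 higher and 5 lower genes with the largest change among those past the threshold, with a mean of at least 2 FPKM in the higher group replicates that did not overlap and no clone or pseudogene name, up to 3 members per list past the threshold by smallest p, and a panel of bone, metallothionein and mechanosensing genes whether past it or not; the text leaves some members out for length. No gene passed, so, after the data were seen, the first part was applied at an unadjusted p under 0.01 and the second at an unadjusted p under 0.05. Genes outside this rule, such as Saa3, Thy1, Kap, Gm43302, Parp9 and the Y-linked genes, were chosen after their values were seen.

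The test was run on simulated counts for ultrasound on PLLA, over 11936 genes with 200 changed. At the spread of these libraries it recovered 4, 24, 38 and 40 of 50 genes changed 1.5-, 2-, 3- and 4-fold, with 6 false calls. The simulated genes varied independently and no simulated library stood apart from its group. The real data differ in both, so these rates may not hold for them. Alternatives covered DESeq2 1.42.0, DESeq2 size factors, limma with other pseudocounts, scalings, priors and library weights, other filters on low values, a fold threshold, a replicate block, fits of only the libraries compared, and each library left out. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom was 15.95. No library was left out of the main test.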

Results

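Messenger RNA was sequenced from MC3T3-E1 cells, a mouse pre-osteoblast line, grown for 5 days on 15 mm discs of fibre membrane after seeding at 20000 cells per well. The membranes were plain PLLA (a biodegradable polyester), PLLA with zinc oxide (PLLA/ZnO), and PLLA/ZnO with collagen (PLLA/ZnO@Col). Each was used without ultrasound (-US) or with ultrasound for 10 min every day (+US), which gave 6 groups of 3 libraries, 18 in all. The series addresses whether these piezoelectric membranes promote bone formation. Gene counts summed to between 48307580 and 78039543 per library. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Changes are log2 fold changes with standard errors (SE), levels are FPKM as mean ± SD with n = 3 per group, and coordinates are GRCm38.

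Col1a1 and Spp1 were abundant in these cells and several other osteoblast markers were not. Col1a1, the main collagen of bone (chromosome 11, 94936224 to 94953042), lay between 500 and 1160 FPKM over the 18 libraries. Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), lay between 637 and 3610 FPKM, and Runx2, the osteoblast transcription factor (chromosome 17, 44495987 to 44814797), between 6.22 and 9.54. Sp7, Alpl, Bglap and Ibsp, markers of earlier and later osteoblast differentiation, reached at most 0.746, 0.178, 0.626 and 0.0286 FPKM and were too low to test. The list for osteoblast differentiation and mineralisation (13 of 24 genes tested) was not called in any of the 7 comparisons between groups, with a smallest adjusted p of 0.232 (camera). Neither were heat shock genes (smallest adjusted p = 0.145) or osteocyte markers (5 genes tested, smallest adjusted p = 0.377).

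Some libraries stood apart from their groups. PLLA/ZnO@Col -US replicates 1 and 3 and PLLA/ZnO@Col +US replicate 1 held 1.48%, 2.19% and 2.75% of the reads expected from Ddx3y, Eif2s3y, Kdm5d and Uty, 4 genes of the Y chromosome. These 3 libraries lay at 0.48, 0.53 and 0.47 on the second principal component, and the next highest library lay at 0.05. Saa3, an acute-phase protein gene, was at 2.95, 10.7 and 3.5 FPKM in them, and Thy1, a surface marker of mesenchymal cells, at 0.0709, 0.128 and 0.115. Fits without these 3 libraries leave replicate 2 as the only PLLA/ZnO@Col -US library, which is then assumed to vary like the libraries of the other groups. In PLLA/ZnO@Col -US replicate 2, Saa3 was at 75.8 and Thy1 at 2.55 FPKM. PLLA +US replicate 3, PLLA/ZnO +US replicate 3 and PLLA/ZnO@Col +US replicates 2 and 3 held 33.4%, 16.9%, 36.7% and 41.4% of the expected Y-linked reads. They lay at 0.25, 0.56, 0.34 and 0.22 on the first component, with 1.87%, 1.57%, 1.58% and 1.77% of counts from mitochondrial genes, and PLLA/ZnO@Col -US replicate 3 lay at 0.29 with 1.83%. PLLA/ZnO@Col +US replicates 2 and 3 had correlations of 0.982 and 0.985 with PLLA +US replicate 3, and of 0.952 and 0.956 with replicate 1 of their own group. Within groups the lowest correlation between replicates was 0.894 in PLLA/ZnO@Col -US and 0.925 in PLLA/ZnO +US.

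**Figure D1:**
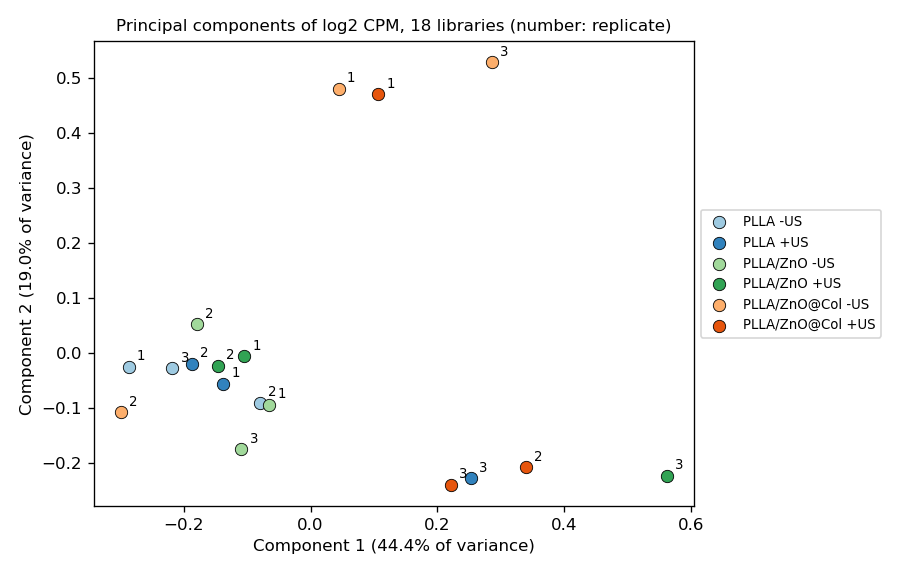
Each point is 1 of the 18 libraries, placed by its first (44.4% of variance) and second (19% of variance) principal component of log2 CPM, coloured by group and numbered by replicate. The 3 points at 0.47 or more on the second component are PLLA/ZnO@Col -US replicates 1 and 3 and PLLA/ZnO@Col +US replicate 1.

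**Figure D2:**
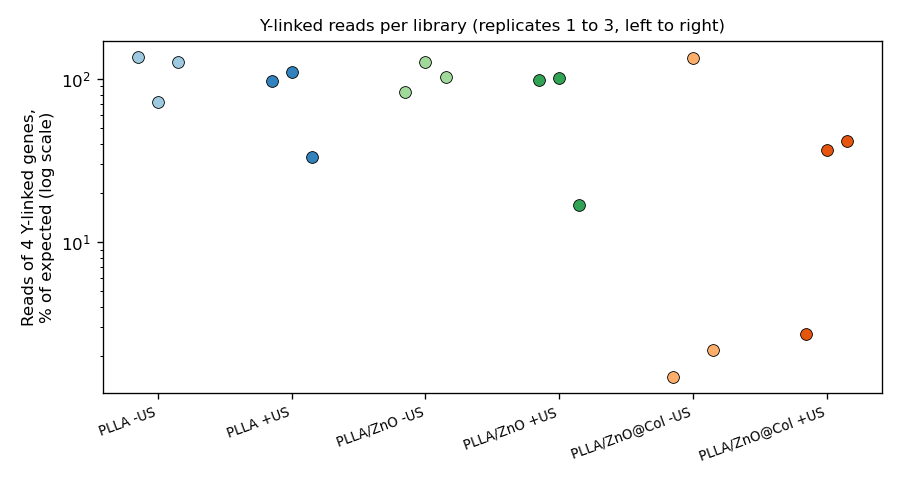
Reads of Ddx3y, Eif2s3y, Kdm5d and Uty in each library, as a percent of the reads expected from the library total and the median rate of the 12 libraries without collagen, on a log axis; points are single libraries in replicate order. Values of 1.48%, 2.19% and 2.75% belong to 3 PLLA/ZnO@Col libraries, and the next lowest, 16.9%, to PLLA/ZnO +US replicate 3.

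On plain PLLA, no bone gene passed the test between cells with and without ultrasound. Col1a1 was at 958 ± 68.9 with ultrasound and 863 ± 122 without (log2 fold change 0.12, SE 0.22, adjusted p = 0.978), and Runx2 at 8.57 ± 0.525 and 9.13 ± 0.377 (-0.12, SE 0.20, adjusted p = 0.978). Genes of the antioxidant response were higher as a list, in 24 of 29 members (median log2 fold change 0.20, camera adjusted p = 0.000231), as were immediate early genes in 21 of 26 (median 0.16, adjusted p = 0.0156). With an estimated correlation both adjusted p-values were 0.984, and no member of either passed over all genes or adjusted over the list alone. Macrophage and osteoclast markers were lower in 7 of 8 (median -0.60, adjusted p = 0.0306, and 0.984 with an estimated correlation). Cell cycle, nuclear oxidative phosphorylation and ribosomal protein genes were the other called lists, all upward (adjusted p = 0.0306, 0.042 and 0.042, each 0.984 with an estimated correlation), with 0 members past either adjustment. Gpx3, an extracellular glutathione peroxidase in the antioxidant list (chromosome 11, 54902453 to 54910377), was at 8.47 ± 12.7 against 1.18 ± 0.0863, and its 23.2 FPKM in PLLA +US replicate 3 came with Kap, an androgen-regulated kidney gene, at 62.4 FPKM. In edgeR's quasi-likelihood test 0 of 11936 genes passed (smallest adjusted p = 0.978), and DESeq2 and limma also called 0. An unadjusted p under 0.05 was found for 52, where 597 genes were expected by chance. The expected number is the same in every contrast. Lower counts, here and below, give no lead to changed genes and do not show that none changed. Genes are not independent, so higher counts are no test of change either. Among the libraries with ultrasound, PLLA +US replicate 3 held 33.4% of the expected Y-linked reads.

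On PLLA/ZnO, genes of glycolysis and hypoxia were lower with ultrasound in 28 of 28 tested members (median log2 fold change -0.41, camera adjusted p = 6.83e-13, and adjusted p = 0.273 with an estimated correlation). No member passed over all genes and 4 passed adjusted over the list alone. Bnip3, a mitophagy gene induced by low oxygen (chromosome 7, 138890836 to 138909519), was at 30.95 ± 3.73 with ultrasound and 69.7 ± 18.1 without (-1.17, SE 0.24). Pdk1, which restrains pyruvate oxidation in mitochondria (chromosome 2, 71873224 to 71903858), was at 8.53 ± 1.09 and 15.7 ± 2.72 (-0.88, SE 0.18). Car9, a carbonic anhydrase of hypoxic cells (chromosome 4, 43506966 to 43513729), was at 4.00 ± 1.20 and 11.8 ± 8.06 (-1.56, SE 0.44). Each of the 3 had an adjusted p of 0.937. Cell cycle genes were higher in 25 of 33 (median 0.19, adjusted p = 1.89e-06, and 0.283 with an estimated correlation), among them Plk1, a mitotic kinase, at 69.7 ± 11.7 and 48.02 ± 1.70 (0.54, SE 0.17, adjusted p = 0.937). Contractile actin genes were higher in 16 of 19 (median 0.18, adjusted p = 0.0165) and antioxidant genes in 24 of 29 (median 0.11, adjusted p = 0.0488), both at 0.622 with an estimated correlation. In these 3 lists 0 members passed over all genes or adjusted over the list alone.

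Lists of interferon response and of inflammatory cytokines were lower on PLLA/ZnO with ultrasound, in 29 of 31 (median -0.38, adjusted p = 4.04e-06) and 21 of 24 members (median -0.36, adjusted p = 0.000225). With an estimated correlation these adjusted p-values were 0.369 and 0.602, and no member passed over all genes or adjusted over the list alone. Cxcl5, a neutrophil chemokine, was at 25.6 ± 7.16 and 58.7 ± 18.3 (-1.19, SE 0.56, adjusted p = 0.937). By edgeR 0 of 11936 genes passed (smallest adjusted p = 0.937) and 387 had an unadjusted p under 0.05; limma called 0. PLLA/ZnO +US replicate 3 held 16.9% of the expected Y-linked reads. DESeq2 called 5, Pdk1, Bnip3, Ak4, Gm20521 and Gm49909, of which the last 3 were chosen after their values were seen. Without PLLA/ZnO +US replicate 2, edgeR called 1 gene, Gm43302, and without PLLA/ZnO -US replicate 2 camera called 12 lists in place of 6.

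On the collagen membrane, matrix genes were higher with ultrasound as a list at the preset correlation, a call that was lost with an estimated correlation (adjusted p = 0.538) and without the 3 libraries lacking Y-linked reads (adjusted p = 0.139), and no single gene passed. Col6a1 and Col6a2, chains of the pericellular collagen VI, were at 253 ± 47.9 against 144 ± 13.6 (0.81, SE 0.21) and 82.5 ± 16.5 against 45.3 ± 3.83 (0.86, SE 0.21), each with an adjusted p of 0.525. Both lie on chromosome 10, at 76708792 to 76726168 and 76595762 to 76623630. Fibrillar and associated matrix genes were higher in 19 of 25 (median 0.25, camera adjusted p = 0.000391), with 0 passing over all genes and 3 adjusted over the list alone, and collagen processing genes in 17 of 20 (median 0.23, adjusted p = 0.00124), with 0 and 1. Wnt signalling genes were higher in 18 of 23 (median 0.27, adjusted p = 0.000541), with 0 and 3, among them Axin2, a feedback inhibitor of the pathway (chromosome 11, 108920349 to 108950783), at 1.41 ± 0.388 against 0.702 ± 0.176 (1.0, SE 0.27, adjusted p = 0.525). Each of the 3 lists had an adjusted p of 0.538 with an estimated correlation. The reference, PLLA/ZnO@Col -US, is also the collagen group in the contrast of collagen without ultrasound. Matrix and Wnt genes were called lower there, and both contrasts share the chance deviations of this group. Without the 3 libraries that lacked Y-linked reads, with 1 library left without ultrasound, the matrix and Wnt calls ended (adjusted p = 0.139 and 0.22), and the collagen processing list had an adjusted p of 0.0119.

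On the same membrane immediate early genes were higher with ultrasound in 22 of 26 (median 0.36, adjusted p = 0.000119, and 0.538 with an estimated correlation), 0 of them past either adjustment, with Egr1, a transcription factor induced by serum and mechanical load (chromosome 18, 34859823 to 34864984), at 81.7 ± 11.4 against 49.3 ± 11.5 (0.74, SE 0.27, adjusted p = 0.525); without the 3 libraries lacking Y-linked reads, again with 1 library left without ultrasound, the call of the list ended (adjusted p = 0.0754). Interferon response genes were higher in 22 of 31 (median 0.17, adjusted p = 0.00391, and 0.538 with an estimated correlation), 0 of them past either adjustment. They were lower in PLLA/ZnO@Col -US than in PLLA/ZnO -US, so both contrasts share the chance deviations of PLLA/ZnO@Col -US. Genes of integrins and focal adhesion (16 of 25 higher), contractile actin (14 of 19), matrix proteases and inhibitors (15 of 21), and BMP and TGF-beta signalling (16 of 28) were called upward at adjusted p = 0.0118, 0.0129, 0.0378 and 0.0459. Their adjusted p-values with an estimated correlation were 0.538, 0.546, 0.546 and 0.546, and 0 members of these 4 lists passed either adjustment. Without the 3 libraries lacking Y-linked reads the integrin, protease and BMP calls ended (adjusted p = 0.258, 0.22 and 0.939) and the protease list had the opposite direction, with 1 library left without ultrasound. Transcripts encoded by mitochondria were lower in 13 of 13 (median -0.60, adjusted p = 0.0017, and 0.546 with an estimated correlation), 0 of them past either adjustment, and PLLA/ZnO@Col -US replicate 2 had the largest mitochondrial share of all libraries (4.54%). No gene of the 11936 passed in edgeR (smallest adjusted p = 0.525), 976 had an unadjusted p under 0.05, limma called 0, and DESeq2 called Tnn, Cthrc1 and Cyp26b1, 3 genes named after their values were seen. PLLA/ZnO@Col +US replicates 2 and 3 held 36.7% and 41.4% of the expected Y-linked reads. Without PLLA/ZnO@Col +US replicate 1 edgeR called 38 genes (30 higher, 8 lower), and without the 3 libraries lacking Y-linked reads, with 1 library left without ultrasound, 111 (70 higher, 41 lower).

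Zinc oxide in the membrane, without ultrasound, went with higher levels of hypoxia genes as a list. Glycolysis and hypoxia genes were higher on PLLA/ZnO than on PLLA in 26 of 28 (median 0.43, camera adjusted p = 1.29e-18, and adjusted p = 0.0845 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Bnip3 was at 69.7 ± 18.1 against 41.7 ± 3.56 (0.75, SE 0.23, adjusted p = 1). These libraries are also the reference for ultrasound on PLLA/ZnO, so both contrasts share their chance deviations. Mt1 and Mt2, which encode zinc-binding metallothioneins (chromosome 8, 94179082 to 94180327 and 94172664 to 94173568), were at 135 ± 13.8 against 84.7 ± 2.98 (0.68, SE 0.29) and 382 ± 52.3 against 257 ± 17.3 (0.58, SE 0.27), each with an adjusted p of 1. The list of zinc transporters and metallothioneins was not called in this contrast.

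Ribosomal protein genes were higher on PLLA/ZnO without ultrasound in 36 of 36 (median 0.33, adjusted p = 1.1e-12) and nuclear oxidative phosphorylation genes in 30 of 30 (median 0.28, adjusted p = 8.62e-10), both at an adjusted p of 0.529 with an estimated correlation. Reads of ribosomal protein genes can be split with their pseudogenes, so single members are uncertain. Immediate early genes were lower in 21 of 26 (median -0.20, adjusted p = 2.37e-06), with Egr1 at 25.4 ± 1.39 against 46.4 ± 18.5 (-0.86, SE 0.27, adjusted p = 1). Antioxidant genes were called upward at adjusted p = 0.0027, and these last 2 lists also had an adjusted p of 0.529 with an estimated correlation. In the 4 lists no member passed over all genes or adjusted over the list alone. YAP and TAZ targets (15 of 21 lower), mechanosensitive and calcium signalling genes (25 of 31 lower), inflammatory genes (16 of 24 lower) and macrophage markers (7 of 8 lower) were called downward at adjusted p = 0.0139, 0.0288, 0.0419 and 0.0416, against 0.629, 0.529, 0.629 and 0.629 with an estimated correlation. Collagen processing and cholesterol synthesis genes were called upward at adjusted p = 0.0288 and 0.0319, both at 0.629 with an estimated correlation, and 0 members of these 6 lists passed either adjustment. The edgeR test called 0 of 11936 genes (smallest adjusted p = 0.861), 142 had an unadjusted p under 0.05, limma called 0, and DESeq2 called 1, Gm10874, named after its values were seen. Without PLLA -US replicate 1 camera called 7 lists in place of 11.

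With ultrasound, cells on PLLA/ZnO had lower levels of immediate early and inflammatory genes than cells on PLLA. Immediate early genes were lower in 24 of 26 (median -0.31, adjusted p = 2.85e-10), with 0 passing over all genes or adjusted over the list alone, and inflammatory cytokine genes in 22 of 24 (median -0.35, adjusted p = 1.82e-08), with 0 and 1. Both adjusted p-values were 0.27 with an estimated correlation. Fos, an AP-1 subunit (chromosome 12, 85473890 to 85477273), was at 3.41 ± 0.629 against 11.1 ± 4.98 (-1.68, SE 0.61), Egr1 at 33.1 ± 2.01 against 60.2 ± 14.8 (-0.83, SE 0.27), and Tnfaip3, an inhibitor of NF-kB signalling (chromosome 10, 19000910 to 19015410), at 6.19 ± 0.712 against 11.2 ± 0.593 (-0.80, SE 0.19), each with an adjusted p of 1. Ccn1, a matricellular YAP target (chromosome 3, 145646976 to 145649981), was at 110 ± 4.93 against 206 ± 52.7 (-0.88, SE 0.29, adjusted p = 1), and its list was lower in 17 of 21 (adjusted p = 0.00616, and 0.582 with an estimated correlation). Ribosomal protein genes were higher in 36 of 36 (median 0.28, adjusted p = 3.06e-12) and nuclear oxidative phosphorylation genes in 29 of 30 (median 0.21, adjusted p = 8.5e-09), both at 0.582 with an estimated correlation. In the YAP, ribosomal and oxidative phosphorylation lists 0 members passed either adjustment.

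A further 5 lists were called for zinc oxide with ultrasound. Cholesterol synthesis, contractile actin and antioxidant genes were called upward (adjusted p = 0.00732, 0.00808 and 0.0399; 0.708, 0.644 and 0.659 with an estimated correlation). Interferon response and zinc genes were called downward (adjusted p = 0.0071 and 0.0383; 0.644 and 0.27 with an estimated correlation), and 0 members of the 5 lists passed either adjustment. In the zinc list 14 of 18 were lower (median -0.14), and Mt1 was at 95.8 ± 15.0 against 109 ± 29.6 (-0.14, SE 0.28, adjusted p = 1). PLLA/ZnO +US replicate 3 and PLLA +US replicate 3, which stood apart from their groups, both enter this contrast; without PLLA +US replicate 3 camera called 6 lists in place of 10. By edgeR 0 of 11936 genes passed (smallest adjusted p = 1) and 151 had an unadjusted p under 0.05; limma called 0, and DESeq2 called Gm20521 and Gm49909, 2 genes named after their values were seen. Without PLLA/ZnO +US replicate 2 edgeR called 1 gene, Gm43302.

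Collagen on the PLLA/ZnO membrane, without ultrasound, went with lower levels of interferon response genes, in 29 of 31 tested members (median -0.95, camera adjusted p = 3.34e-27). Of the list calls in the 7 comparisons between groups this was the only one that held with an estimated correlation (adjusted p = 0.01), and fry gave an adjusted p of 0.00106. No member passed over all genes and 20 passed adjusted over the list alone. Ifit3, an interferon-induced inhibitor of viral replication (chromosome 19, 34583531 to 34588731), was at 2.28 ± 0.768 with collagen and 9.55 ± 4.95 without (-2.04, SE 0.40, adjusted p = 0.069), and Oasl2, an oligoadenylate synthetase-like gene (chromosome 5, 114896936 to 114912234), at 1.41 ± 0.415 against 3.60 ± 0.825 (-1.33, SE 0.26, adjusted p = 0.0685). PLLA/ZnO@Col -US replicates 1 and 3 are among the libraries lacking Y-linked reads. In PLLA/ZnO -US, the reference, Ifit3 was at 14.99, 5.304 and 8.364 FPKM in replicates 1, 2 and 3. Without replicate 1 of that group, 29 of 31 members were lower (median -0.685) and 14 passed adjusted over the list alone. The camera adjusted p with an estimated correlation was then 0.0146. This group is also the reference for ultrasound on PLLA/ZnO, where the list was lower too, so both contrasts share its chance deviations. Without PLLA/ZnO@Col -US replicate 2, 28 of 31 members were lower (median -0.904). The camera adjusted p with an estimated correlation was then 0.335, and fry gave an adjusted p of 0.00903. Without the 3 libraries lacking Y-linked reads, 30 of 31 were lower (median -0.949). That fit leaves 1 library with collagen, so its spread was not measured.

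Single genes had distant means on the membranes with and without collagen, without ultrasound, and did not pass the test. Cyp1a1, a target of the aryl hydrocarbon receptor (chromosome 9, 57687928 to 57703824), was at 9.96 ± 3.90 against 2.53 ± 0.222 (2.02, SE 0.34, adjusted p = 0.0673). With collagen it was at 12.69 and 11.68 FPKM in the libraries lacking Y-linked reads and at 5.493 in replicate 2. Bmp4, a bone morphogenetic protein (chromosome 14, 46383520 to 46390669), was at 1.59 ± 0.901 against 7.94 ± 0.607 (-2.30, SE 0.46, adjusted p = 0.0703), and Tgfb1 (chromosome 7, 25687002 to 25705077) at 12.3 ± 1.55 against 6.69 ± 0.331 (0.91, SE 0.17, adjusted p = 0.0673). Ccl5, a T cell chemokine (chromosome 11, 83525778 to 83530518), was at 5.23 ± 5.72 against 40.9 ± 3.97 (-2.96, SE 0.76, adjusted p = 0.121), with 1.67 and 2.18 FPKM in the libraries lacking Y-linked reads and 11.8 in replicate 2. Piezo1, a mechanically gated cation channel (chromosome 8, 122481698 to 122551329), was at 40.4 ± 11.02 against 22.5 ± 5.30 (0.88, SE 0.21, adjusted p = 0.106).

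Among the other lists for collagen without ultrasound, Wnt signalling genes were lower in 18 of 23 (median -0.45, adjusted p = 1.99e-06) and inflammatory cytokine genes in 15 of 24 (median -0.49, adjusted p = 0.000477), each with 0 passing over all genes, 4 adjusted over the list alone, and an adjusted p of 0.574 with an estimated correlation. Without the 3 libraries lacking Y-linked reads, which leaves 1 library with collagen, the Wnt call ended (adjusted p = 0.123), the inflammatory list had the opposite direction, uncalled (adjusted p = 0.636), and the call of ER stress genes, given next, ended (adjusted p = 0.321). Glycolysis and hypoxia genes were lower in 20 of 28 (adjusted p = 0.000477), fibrillar matrix genes in 17 of 25 (adjusted p = 0.00646), immediate early genes were higher in 21 of 26 (adjusted p = 0.000846) and ER stress genes in 17 of 24 (adjusted p = 0.00731). With an estimated correlation these adjusted p-values were 0.574, 0.664, 0.574 and 0.574; adjusted over the list alone 2, 2, 3 and 2 members passed. Ribosomal protein genes were called downward (adjusted p = 0.00663, and 0.864 with an estimated correlation) although 18 of 36 were higher and the median was -0.0046. Fibroblast markers were called downward (adjusted p = 0.044, and 0.574 with an estimated correlation) with 7 of 13 lower, 2 of them past adjustment over the list alone. The reference here, PLLA/ZnO -US, is also the group in which immediate early genes were lower and glycolysis and hypoxia genes higher than on PLLA. For these lists the collagen and zinc oxide contrasts therefore share chance deviations of that group.

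For collagen without ultrasound, edgeR called 0 of 11936 genes (smallest adjusted p = 0.0673), 1544 had an unadjusted p under 0.05, limma called 0, and DESeq2 called 407 (256 higher, 151 lower). The edgeR count depended on single libraries: it was 1039 (657 higher, 382 lower) without PLLA/ZnO@Col -US replicate 2, 18 without PLLA/ZnO@Col -US replicate 3, 41 without PLLA/ZnO +US replicate 3, 95 without PLLA/ZnO@Col +US replicate 1, and 166 (67 higher, 99 lower) without the 3 libraries lacking Y-linked reads, from 1 library with collagen.

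With ultrasound, cells on the collagen membrane had higher levels of immediate early genes than cells on PLLA/ZnO, in 26 of 26 tested members (median 0.57, camera adjusted p = 1.79e-14, and adjusted p = 0.191 with an estimated correlation). No member passed over all genes and 5 passed adjusted over the list alone. Egr1 was at 81.7 ± 11.4 against 33.1 ± 2.01 (1.34, SE 0.28, adjusted p = 0.339), and Fos at 11.97 ± 3.24 against 3.41 ± 0.629 (1.84, SE 0.61, adjusted p = 0.415). Ccn1 and Ccn2, YAP targets, were at 296 ± 53.6 against 110 ± 4.93 (1.46, SE 0.29, adjusted p = 0.339) and 9.64 ± 2.39 against 4.19 ± 0.304 (1.24, SE 0.33, adjusted p = 0.404), in a list higher in 16 of 21 (adjusted p = 0.0118, and 0.798 with an estimated correlation; 2 adjusted over the list alone). Piezo1 was at 44.1 ± 6.65 against 27.3 ± 2.36 (0.73, SE 0.21, adjusted p = 0.415). The PLLA/ZnO +US libraries are also those in which immediate early genes were lower than on PLLA, so the 2 contrasts share their chance deviations.

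**Figure D3:**
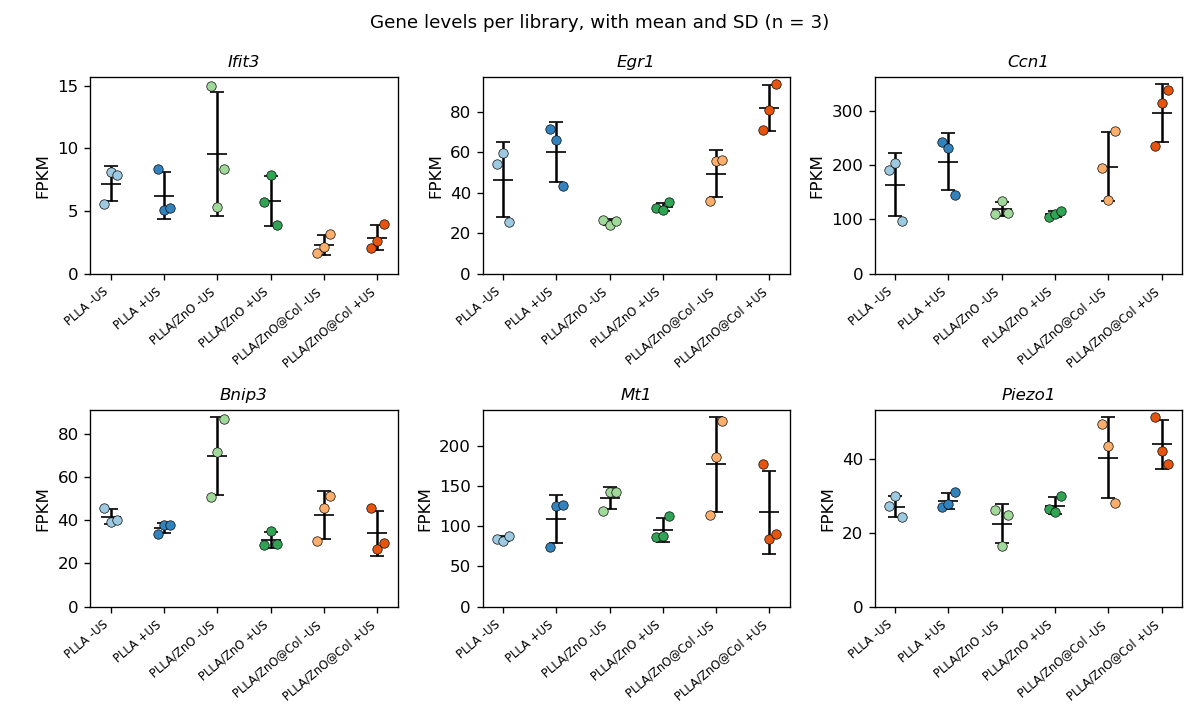
FPKM of Ifit3, Egr1, Ccn1, Bnip3, Mt1 and Piezo1 in each of the 6 groups; coloured points are the 3 libraries, the horizontal mark is the mean and the bars are 1 SD. Ifit3 averaged 2.28 FPKM on PLLA/ZnO@Col -US and 9.55 on PLLA/ZnO -US, and Bnip3 averaged 69.7 on PLLA/ZnO -US and 30.95 on PLLA/ZnO +US; no difference passed edgeR's test over all genes.

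Interferon response genes were lower on the collagen membrane with ultrasound too, in 24 of 31 (median -0.29, adjusted p = 1.57e-05, and 0.554 with an estimated correlation). Without PLLA/ZnO@Col +US replicate 1 it was 21 of 31 (median -0.175, adjusted p = 0.021), and without the 3 libraries lacking Y-linked reads 23 of 31 (median -0.203, adjusted p = 0.0205). Ribosomal protein genes were lower in 31 of 36 (adjusted p = 0.000263), mitochondrially encoded transcripts in 13 of 13 (adjusted p = 0.0011) and nuclear oxidative phosphorylation genes in 21 of 30 (adjusted p = 0.0118). Collagen processing (17 of 20 higher), glycolysis and hypoxia (24 of 28) and integrin genes (15 of 25) were called upward at adjusted p = 0.00511, 0.0249 and 0.0487. All 6 had an adjusted p of 0.798 with an estimated correlation, and adjusted over the list alone 3 ribosomal protein genes passed and 0 of the others. Without the 3 libraries lacking Y-linked reads the glycolysis and oxidative phosphorylation calls ended (adjusted p = 0.109 and 0.0504). By edgeR 0 of 11936 genes passed (smallest adjusted p = 0.339) and 1125 had an unadjusted p under 0.05; limma called 0 and DESeq2 called 47 (34 higher, 13 lower). Without PLLA/ZnO +US replicate 3 camera called 5 lists in place of 9.

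Averaged over the 3 membranes, the ultrasound contrast gave 0 genes in edgeR (smallest adjusted p = 0.363) and 0 in limma, with 1444 at an unadjusted p under 0.05, and DESeq2 called 1, Gm6402, named after its values were seen. Without PLLA/ZnO +US replicate 2 edgeR called 1, Gm43302. The fit without the 3 libraries lacking Y-linked reads has 1 PLLA/ZnO@Col -US library left, and its count is not read as a response to ultrasound. Libraries with 16.9% to 41.4% of the expected Y-linked reads are then in the +US group of each membrane. The -US libraries in that fit held 72% to 136%, so the averaged contrast cannot be told apart from this difference. The difference of the ultrasound response between PLLA/ZnO and PLLA gave 0 genes in edgeR, DESeq2 and limma (smallest edgeR adjusted p = 1) and 46 at an unadjusted p under 0.05. Between PLLA/ZnO@Col and PLLA/ZnO it gave 0 in all 3 tools (smallest edgeR adjusted p = 0.999) and 263 at an unadjusted p under 0.05, and edgeR called 13 without the 3 libraries, again with 1 PLLA/ZnO@Col -US library. Each difference gave 1 gene, Gm43302, without PLLA/ZnO +US replicate 2. Differences of a list between membranes were not tested.

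The ultrasound responses on separate membranes, which share no libraries, were correlated across the 11936 genes. Pearson's r was 0.51 between PLLA and PLLA/ZnO (Spearman's rho 0.609), 0.429 between PLLA and PLLA/ZnO@Col (0.547) and 0.373 between PLLA/ZnO and PLLA/ZnO@Col (0.531). The zinc oxide responses without and with ultrasound gave r = 0.415 (rho 0.523) and the collagen responses r = 0.43 (rho 0.531). Genes are not independent replicates, so no p-value is given. Libraries with 16.9% to 41.4% of the expected Y-linked reads were in the +US group of each membrane and in no group without ultrasound. These values rested on few libraries: without PLLA/ZnO +US replicate 3 the first, the third and the zinc oxide values were 0.115, -0.0185 and 0.119, and without PLLA/ZnO@Col -US replicate 2 the second and the third were 0.064 and 0.0369. Without PLLA +US replicate 3 the first 2 were 0.235 and 0.099, and without PLLA -US replicate 1 the second was 0.25. The third was 0.161 without PLLA/ZnO -US replicate 2, and the collagen value was 0.121 without PLLA/ZnO@Col +US replicate 1 and 0.27 without PLLA/ZnO -US replicate 2.

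A contrast of collagen, zinc oxide and ultrasound together, PLLA/ZnO@Col +US against PLLA -US, was added after the data were seen. It gave 0 of 11936 genes in edgeR (smallest adjusted p = 0.168), 3185 at an unadjusted p under 0.05, 0 in limma and 168 in DESeq2 (94 higher, 74 lower). Interferon response genes were lower in 27 of 31 (median -0.55, adjusted p = 4.41e-07, and 0.675 with an estimated correlation), with 0 passing over all genes and 12 adjusted over the list alone. Immediate early genes were higher in 23 of 26 (adjusted p = 0.00224; 0 and 6), and collagen processing genes in 18 of 20 (adjusted p = 0.0408; 0 and 0), both with an adjusted p of 0.917 with an estimated correlation. Inflammatory genes were lower in 17 of 24 (adjusted p = 0.0233; 0 and 0) and mitochondrially encoded transcripts in 12 of 13 (adjusted p = 0.0323; 0 and 0), also at 0.917 with an estimated correlation. A fit of only those 6 libraries called 3521 genes (1516 higher, 2005 lower), and without PLLA/ZnO +US replicate 3, which is outside the contrast, edgeR called 1, Parp9.

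Few adipocyte, chondrocyte, endothelial or epithelial markers reached the tested level. Of the adipocyte list only Plin2 and Pnpla2 were tested; for collagen without ultrasound both passed adjusted over the list alone, at 34.2 ± 5.80 against 22.97 ± 1.72 and 8.84 ± 1.62 against 7.27 ± 0.257, and neither over all genes (adjusted p = 0.147 and 0.341). Sox9 was the tested chondrocyte marker, with log2 fold changes from -0.14 to 0.34 over the 7 comparisons, and Flt1 the tested endothelial one, from -1.13 to 0.68. No epithelial marker reached the minimum level.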

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

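Chosen after the data were seen were limma on log2(FPKM + 1) as an alternative, DESeq2 and its size factors, limma voom with library weights, a term for the 3 libraries lacking Y-linked reads, the fits without them and without PLLA/ZnO@Col -US replicate 2 with +US replicate 1, the checks of the interferon list, leaving out libraries outside a contrast, all results of the contrast of collagen, zinc oxide and ultrasound together, the shuffles of replicate numbers, and the list tests and correlations with a library left out. The 11 contrasts gave 0 genes in the main test. They also gave 0 with DESeq2 size factors, without a filter, at an FPKM minimum of 5, with a fold threshold, with limma on log2(FPKM + 1), with other priors, with quantile scaling and with a term for the 3 libraries. Below, the cause of a moved value was not tested unless stated.

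DESeq2 called 5 genes for ultrasound on PLLA/ZnO, 3 for ultrasound on PLLA/ZnO@Col, 1 and 2 for zinc oxide without and with ultrasound, 407 and 47 for collagen without and with ultrasound, 1 for the average and 168 for the combined contrast. For collagen without ultrasound limma called 1 gene, Alox5ap, with a pseudocount of 0.1 and 1, the same gene, with TPM; it was named after its values were seen. A fit of only its own libraries called 3521 genes in the combined contrast. Limma with library weights called 134, 2236 and 7319 genes for ultrasound on PLLA, PLLA/ZnO and PLLA/ZnO@Col, 2737 and 1258 for zinc oxide without and with ultrasound, 8154 and 6792 for collagen without and with it, 4900 for the average, 1163 and 6897 for the differences between membranes, and 7454 for the combined contrast. These weights ran from 0.097 to 83.5, their fit did not converge, and over 20 random relabellings of the libraries the largest count in a contrast had a median of 6230.5 genes, so these counts are not calibrated. Limma voom with library weights called, in the same order, 1, 568, 3370, 1192, 8, 3982, 6086, 1337, 0, 3676 and 7570 genes, and its calibration was not tested.

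Without the 3 libraries lacking Y-linked reads PLLA/ZnO@Col -US holds 1 library, assumed to vary like the other groups, and edgeR called 111 genes for ultrasound on PLLA/ZnO@Col, 166 for collagen without ultrasound, 1044 for the average and 13 for the difference between PLLA/ZnO@Col and PLLA/ZnO. In that fit only +US libraries were low in Y-linked reads, so ultrasound cannot be told apart from this state. Without PLLA/ZnO@Col -US replicate 2 and +US replicate 1 the counts for the same contrasts were 597, 1367, 157 and 323. PLLA/ZnO@Col -US then keeps replicates 1 and 3, with 1.48% and 2.19% of the expected Y-linked reads. PLLA/ZnO@Col +US keeps replicates 2 and 3, with 36.7% and 41.4%. Neither ultrasound on this membrane nor collagen without ultrasound can then be told apart from the lack of Y-linked reads. With 1 library left out the count ranged from 0 to 1 for ultrasound on PLLA/ZnO, zinc oxide with ultrasound, the average, both differences and the combined contrast, from 0 to 38 for ultrasound on PLLA/ZnO@Col and from 0 to 1039 for collagen without ultrasound; it was 0 throughout for the other 3 contrasts.

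Of the 26 lists, camera called 6, 6, 10, 11, 10, 9 and 9 in the 3 ultrasound, 2 zinc oxide and 2 collagen contrasts. An estimated correlation and fry each left 0, except 1 for collagen without ultrasound. Quantile scaling gave 3 lists for ultrasound on PLLA and 6 on PLLA/ZnO@Col, and an FPKM minimum of 5 gave 2 for ultrasound on PLLA. With 1 library left out the counts ranged from 4 to 6, 4 to 12, 7 to 13, 7 to 14, 6 to 11, 7 to 10 and 5 to 12. The correlations between responses ranged from 0.115 to 0.593, 0.064 to 0.601 and -0.0185 to 0.478 for the 3 pairs of ultrasound responses, from 0.119 to 0.468 for zinc oxide and from 0.121 to 0.504 for collagen. The value of -0.0185, a turn of direction, came without PLLA/ZnO +US replicate 3.

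With the replicate number as a replicate block edgeR called 0 genes in all 11 contrasts, and camera called 6, 6, 11, 11, 10, 9 and 9 lists. Deviations of same-numbered libraries had correlations from -0.513 to 0.731, over 0.1 in 8, 6 and 7 of 15 pairs for replicates 1, 2 and 3, so the numbers were not taken to pair the samples. Of 18 libraries 11 correlated best with their own number, against a mean of 6 in 10000 shuffles of the numbers within groups, of which 652 gave as many (one-sided permutation p = 0.0652). The 371 values of named genes had 12925 values under 35 alternatives, of which 137, in 39 of them, changed sign and 929 passed the threshold.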

Other observations

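The tests of the 3 libraries lacking Y-linked reads, of ultrasound as a source of the transcripts in PLLA +US replicate 3 and of the splits were chosen after the result was seen; the others in this part were not.

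In PLLA/ZnO@Col -US replicates 1 and 3 and +US replicate 1, the libraries lacking Y-linked reads, Nme4 was at 0.0614, 0.19 and 0.146 FPKM, Trim44 at 0.24, 0.13 and 0.175, and Igf2 at 0, 0.0697 and 0.00075, and in the other 15 libraries these genes were at 4.51 to 9.14, 1.98 to 5.37 and 3.75 to 7.48 FPKM. Gpx3 was at 1.59, 1.57 and 1.62 FPKM in the 3. In -US replicate 2 and +US replicates 2 and 3, the other libraries of that membrane, it was at 0.0616, 0.11 and 0.107. On the other membranes it was at 1.07 to 2.11 FPKM, apart from 23.2 in PLLA +US replicate 3. For this gene the other libraries of the collagen membrane stood apart, and the 3 did not. The collagen membrane as the source is argued against, because PLLA/ZnO@Col -US replicate 2 held 134% of the expected Y-linked reads, and so is low depth, because at least 5667 such reads were expected in each of the 3. An exchange of labels between PLLA/ZnO@Col -US replicate 2 and +US replicate 1 stays open. Replicate 2 had a mean correlation of 0.931 with +US replicates 2 and 3, and 0.972 with the PLLA -US libraries. On the other membranes 12 replicate pairs had 0.925 to 0.991, the lowest being a pair with PLLA/ZnO +US replicate 3, which stood apart. PLLA/ZnO@Col +US replicate 1 had 0.985 and 0.97 with -US replicates 1 and 3. With replicates 2 and 3 of its own label it had 0.952 and 0.956. These last values would be met under an exchange, but also if the 3 libraries shared another source of cells. Cells of another stock or subclone may also have entered the 3 libraries, which no value here tests.

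PLLA +US replicate 3 alone held transcripts of other tissues: Kap at 62.4, Gpx3 at 23.2, Mbp (myelin) at 12.2 and Hbb-bs (globin) at 8.61 FPKM. RNA from kidney could account for part of this, since 7 of 18 kidney markers were at 1 FPKM or more and at least 10-fold above every other library. So were 4 of 8 brain, 3 of 7 red blood cell and 1 of 8 liver markers, and 0 of the skeletal muscle and lymphoid ones, so kidney as the only source stays open. Ultrasound on PLLA is argued against, because Kap was at 0 FPKM, or 0% of its level here, in both other libraries of that group.

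The responses to ultrasound on separate membranes had a mean Pearson's r of 0.549 over the 3 pairs, taken on differences of mean log2 CPM rather than on edgeR's fold changes. Chance is argued against, because 91 of 4000 relabellings of the libraries within the membranes gave a value as large (one-sided permutation p = 0.0228), the highest other being 0.681. GC content and length of the transcripts, which explained 32.5%, 29.3% and 38.1% of the 3 responses, stay open as a partial source, since the mean after regression on them was 0.343. A single library stays open as well, since the lowest mean with 1 left out was 0.167, without PLLA/ZnO +US replicate 3. A shared response to ultrasound is a hypothesis that was not separated from the state of PLLA +US replicate 3, PLLA/ZnO +US replicate 3 and PLLA/ZnO@Col +US replicates 2 and 3, with 33.4%, 16.9%, 36.7% and 41.4% of the expected Y-linked reads.

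Each contrast of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. With a real count of 0 every one of the 10 splits gives as many by construction. The highest other split gave 0 genes for ultrasound on PLLA, 1 on PLLA/ZnO and 954 on PLLA/ZnO@Col, 0 and 1 for zinc oxide without and with ultrasound, 0 and 1591 for collagen without and with it, and 0 for the combined contrast. The split with 954 genes set PLLA/ZnO@Col -US replicates 1 and 3 and +US replicate 1 against the rest, and the one with 1591 set PLLA/ZnO@Col +US replicate 1 with PLLA/ZnO +US replicates 1 and 2, which points to a structure of the samples. Over 100 drawn splits the average ultrasound contrast had a real count of 0 and a highest other of 227, the difference between PLLA/ZnO and PLLA 0 and 1, and that between PLLA/ZnO@Col and PLLA/ZnO 0 and 606. With a real count of 0 all 100 give as many by construction, so these splits test nothing about the 3 contrasts.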
